A study of Homo sapiens with 4 samples.

How the data were processed

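RNA sequencing was analysed for 4 libraries, 1 per group, from 2 related prostate carcinoma lines. C4-2B ENZR is an enzalutamide-resistant line kept in 20 µM enzalutamide, an antiandrogen drug, and LNCaP is an androgen-responsive line grown without it. Both were grown in medium with 10% fetal bovine serum. Each line carried either a non-targeting control hairpin or a hairpin against the coding region of MAOA, per the labels. The labels' protocols describe lentiviral delivery with antibiotic selection, total RNA, and single reads of 50 nt from an Illumina HiSeq instrument. They do not say whether both lines received the same hairpin sequence, and the library labels of the knockdowns differ between the lines. The labels carry a lane-like suffix that is shared by the libraries of a line and differs between the lines, so line and library batch cannot be told apart, while each ratio stays within a suffix.

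Per the submitters' processing notes, the tools named were Bowtie2 2.1.0, RSEM 1.2.15 and edgeR, with the hg19 build; an edgeR version, the gene annotation and any filter are not given in the sources used here. The authors deposited 2 tables, 1 per line, of CPM (read counts relative to library size) scaled by the trimmed mean of M-values (TMM), with 25343 genes each. The deposited C4-2B ENZR values were read as CPM. The deposited LNCaP values were treated as a signal on the same scale, because the knockdown column summed to 1064500 after the authors' scaling and the CPM of a plain read total cannot sum to that much. The tables were normalized separately, so every ratio was taken within a table and levels are not compared across them. The tables hold 28 gene symbols that had been turned into dates, and 4 rows share such a symbol; none of these is named.

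All values in each column were whole multiples of 1 read's worth within a tolerance of 0.01 read (100% of values), so read counts were recovered. Recovered totals were 23479051 reads for the C4-2B ENZR control, 23679869 for its knockdown, 52550452 for the LNCaP control and 52012696 for its knockdown. At these depths 3 reads, the limit that a count of 0 allows, equal 0.121 and 0.122 CPM in C4-2B ENZR and 0.0529 and 0.0614 CPM in LNCaP. The deposited scaling of C4-2B ENZR was equal to TMM recomputed on its 2 libraries (log2 0.01 for knockdown over control). In LNCaP the deposited scaling was 0.22 and the recomputed one 0.10, and the source of this difference is not given in the sources used here. The median log2 ratio of genes with a mean CPM of at least 10 was -0.01 in C4-2B ENZR and 0.13 in LNCaP.

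The effect of the knockdown in a line was the log2 of (knockdown CPM + 1)/(control CPM + 1), which understates the change of low genes. Counts of genes used a mean CPM of at least 1 over the 2 libraries and a 2-fold difference. With 1 library per group no p-value was computed within a line, and the exact conditional (Clopper-Pearson) 95% intervals given for single ratios cover counting error only, without the pseudocount. The 27 gene lists, with 426 members that all matched a symbol in the tables (8 through synonyms), were fixed before the data were examined. A list with at least 5 measured members was called apart from other genes where its median lay outside the central 95% of 10000 random lists of the same size, drawn from 20 expression bins.

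Genes were tested over both lines with limma 3.58.1 in R 4.3.3, on the 2 within-line ratios of 13114 genes with a mean CPM of at least 1 in both tables, with 1 residual degree of freedom, a trended empirical Bayes prior and Benjamini-Hochberg adjustment at 0.05. The lines are the replicates in this test, but with 276 prior degrees of freedom the spread between the lines hardly enters its SE and p-values. These mostly measure the size of the mean ratio against a spread pooled over genes, and nothing in the labels shows that libraries came from separate cultures within a group. "Rose" and "fell" are used for genes that passed this test. On simulated counts with known changes the limma step recovered 66% of genes changed 1.5-fold and 97.9% of genes changed 2-fold, among 13018 genes, and called 4 unchanged genes. The simulation gave all genes the same dispersion, and each changed gene the same fold in both lines. It therefore does not show how often genes with unlike spread or unlike ratios in the lines are called wrongly. A difference between the lines could not be tested, because the 4 libraries leave no residual degrees of freedom for it.

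Named genes followed a rule set before the data were examined. It took the 10 highest and 10 lowest ratios per line among genes with a mean CPM of at least 5, the 8 each way with the largest ratio shared by both lines, the 5 each way with the smallest limma p, extreme and most abundant members of the lists, and KLK3, YAP1, GLI1, GLI2, SHH and MAOB, and 4 genes that it names are not reported here. Other choices compared were other pseudocounts (0.1 and 5), other filters on low values, centring on the median ratio, rescaling each library to the same sum (for single ratios and 2-fold counts), random lists without matching, and limma without the trend. Added after seeing the data were limma on ratios rescaled in this way, edgeR 4.0.16 with the deposited scaling and with recomputed TMM, DESeq2 1.42.0, a correction for GC content and transcript length, counts without genes that share sequence, and 6 further gene lists with 167 members.

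Transcript sequences came from GENCODE release 29 (GRCh38), a later build than the hg19 of the files, and were matched by symbol for 13385 of 14483 expressed genes (92.4%). They gave GC content, length, 3' UTRs and, for each gene named or 2-fold apart and for 1000 random expressed genes, the share of its 50-mers found in another gene of the tables. A 7-mer scan counted sequence words in 3' UTRs. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.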

Results

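RNA sequencing compared MAOA knockdown with a control hairpin in C4-2B ENZR and in LNCaP, human prostate cancer lines that are resistant to enzalutamide and androgen-responsive, respectively. MAOA encodes monoamine oxidase A, a mitochondrial enzyme that degrades serotonin and noradrenaline. There was 1 library in each of the 4 groups, so differences within a line have no replicate check. Recovered depth was 23479051 and 23679869 reads for the C4-2B ENZR control and knockdown and 52550452 and 52012696 for those of LNCaP, and the 10 most abundant genes took 4.37% to 5.46% of the reads of a library.

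MAOA was lower in the knockdown library of both lines. In C4-2B ENZR it went from 327 to 219 CPM, which is 66.8% of the control level (log2 ratio -0.58, 95% counting interval -0.63 to -0.53). In LNCaP it went from 445 to 140 CPM, 31.3% of control (log2 ratio -1.67, interval -1.71 to -1.64). MAOB, the other monoamine oxidase, was close to the floor of detection with 1 and 0 reads in C4-2B ENZR and 8 and 3 reads in LNCaP. In the mean of both lines MAOA fell by 1.12 on the log2 scale (limma adjusted p = 4.44e-12). The SE of 0.14 is pooled over genes and does not measure the spread between -0.58 and -1.67. In edgeR with recomputed TMM the adjusted p was 0.0139. Whether the depth of the knockdown differed between the lines was not tested.

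**Figure D1:**
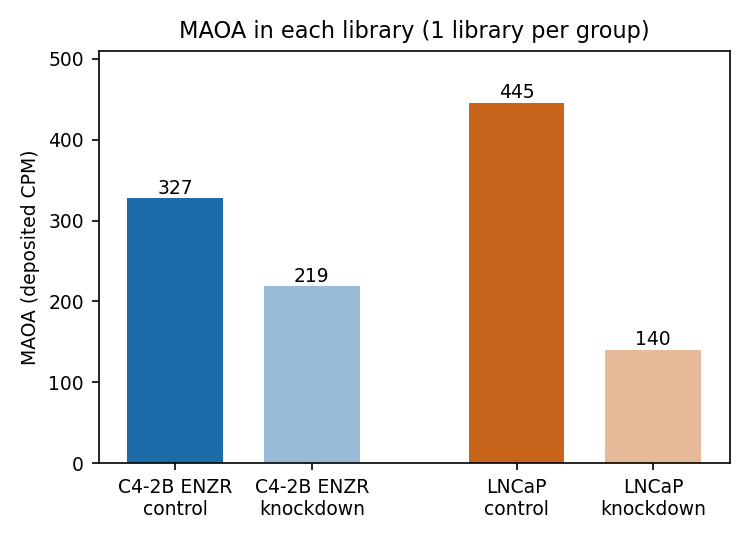
Bars give the deposited CPM of MAOA in each of the 4 libraries, 1 library per bar and no error bars because there are no replicates. The knockdown library was lower in both lines, at 219 against 327 CPM in C4-2B ENZR and 140 against 445 CPM in LNCaP.

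The first question was which transcripts differ when MAOA is silenced in enzalutamide-resistant cells. In C4-2B ENZR the knockdown library had more RNA from genes of the amino acid response, which cells switch on when amino acids run short, and less from genes of DNA replication and mitosis. DDIT4, an inhibitor of mTORC1 signalling, was at 119 CPM in the control and 465 in the knockdown, and CHAC1, which degrades glutathione, had a log2 ratio of 1.52. PLA2G2A, a secreted phospholipase, was at 2.22 and 12.9 CPM (2.11), and SLPI, a protease inhibitor, at 20.3 and 64.7 (1.62). On the lower side were BIRC5, which encodes the apoptosis inhibitor and mitotic protein survivin (175 to 84.4 CPM, -1.04), MDC1, a mediator of the DNA damage checkpoint (217 to 93.8, -1.20), the kappa opioid receptor gene OPRK1 (24.4 to 9.92, -1.22), DAPK1, a death-associated kinase (25.2 to 11.9, -1.02), MINPP1 (31.0 to 15.3, -0.97) and TUBA1A, an alpha-tubulin (49.9 to 21.0, -1.21).

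Of 13810 genes with a mean CPM of at least 1 in C4-2B ENZR, 40 were 2-fold higher and 21 were 2-fold lower in the knockdown library, and the counting interval excluded equality for all 61. With a pseudocount of 0.1 the counts were 90 and 45, and with a pseudocount of 5 they were 18 and 6. Several extreme ratios belonged to genes with near-identical copies. SSX2 was at 75.7 and 1.75 CPM (-4.80) while SSX2B had a ratio of 1.53 and their sum one of 0.09, and all of the 50-mers of SSX2 (100%) occur in another gene. EIF3CL (-1.59, 97.2% shared), SERF1A (-1.20, 90.6%), RPL21P28 (1.93, 75.6%) and GTF2H2C (1.49, 80.4%) share sequence too, so these single-gene values are uncertain. Summed with their copies they were at -0.09, -0.17, 0.27 and -0.31, in this order. LOC100132287 and LOC100132062 had the same values (2.95 and 10.5 CPM), and with NUDT4P1 (log2 2.69, and 1.01 when summed with NUDT4) and C7orf63 (8.65 and 3.62 CPM) they were not searched for copies. Of the genes 2-fold apart and searched, 29.6% shared 50% or more of their 50-mers, against 25 of 1000 random expressed genes. Without such genes 33 were 2-fold higher and 12 were 2-fold lower.

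Of the 23 lists measured in C4-2B ENZR, 5 lay above and 5 below the range of matched random lists, against 1.15 expected outside it if genes varied independently. Genes that are regulated together can differ together between any 2 cultures, so the excess is not a test of the knockdown. ATF4 targets had a median log2 ratio of 0.58, p53 targets 0.21, fatty acid synthesis genes 0.20, NRF2 targets 0.11 and oxidative phosphorylation genes 0.10. FASN, the fatty acid synthase, was at 1026 and 1169 CPM, and COX7C, a subunit of cytochrome c oxidase, at 137 and 214 CPM (0.65). The lower lists were DNA replication (median -0.24), mitosis (-0.19), genes repressed by androgen (-0.57), neuroendocrine markers (-0.27, with 5 measured members) and replication-dependent histones (-0.30). The histone list was chosen as a sign of RNA preparation, but whether that or DNA replication moved it was not tested. Among the androgen-repressed genes OPRK1, UGT2B15 (21.1 to 11.8 CPM) and UGT2B11 (5.01 to 2.77 CPM) were lower, whereas FOLH1, which encodes prostate-specific membrane antigen, was at 994 and 1013 CPM. The neuroendocrine call ended with a pseudocount of 0.1 (percentile 2.69) or 5 (5.25), the NRF2 call with a pseudocount of 5 (90.5) or unmatched random lists (96.0), and the oxidative phosphorylation call with unmatched random lists.

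In LNCaP, the comparison asked the same of cells not selected for drug resistance. The knockdown library had more RNA from ATF4 and p53 targets and less from genes of DNA replication and mitosis. ADRA2A, the alpha-2A adrenergic receptor gene, was at 12.4 CPM in the control and 106 in the knockdown (log2 2.99), and DDC, whose product makes dopamine and serotonin from their precursors, at 3.88 and 19.7 CPM (2.08). S100P was at 11.1 and 68.4 CPM (2.52), CAMK2N1, an inhibitor of CaM kinase II, at 95.5 and 367 (1.93), BBC3, a pro-apoptotic p53 target, at 19.8 and 66.8 (1.71), and DDIT3, the stress transcription factor CHOP, at 19.1 and 64.6 (1.71). BIRC5 was lower (104 to 26.6 CPM, -1.92), and so were MDC1 (200 to 67.0, -1.57), the smooth muscle actin gene ACTA2 (15.3 to 4.95, -1.45), the transcription factor gene RUNX1 (10.9 to 3.52, -1.40), the kinase gene SGK1 (16.0 to 6.32, -1.22), S100A10 (14.8 to 5.79, -1.22) and PPP1R10 (136 to 58.6, -1.20).

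Of 13787 genes with a mean CPM of at least 1 in LNCaP, 80 were 2-fold higher and 35 were 2-fold lower, and all 115 had counting intervals that excluded equality. This split depended on the scaling, since the median ratio of expressed genes was 0.13 above 0. Centred on that median, 48 genes were higher and 58 lower, and with each library rescaled to the same sum 41 were higher and 67 lower. GAGE4 (26.4 to 0 CPM), GAGE2B (0.282 to 27.0 CPM), RGPD6 (-1.11) and the readthrough gene BLOC1S5-TXNDC5 (1.90) belong to families or loci of near-identical copies, the 22 GAGE genes summed were at 0.02, and PCNA-AS1 (-1.23) overlaps PCNA on the other strand, so their values are uncertain.

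Of the 23 lists measured in LNCaP, 7 lay above and 3 below the range of matched random lists, against 1.15 expected outside it if genes varied independently. The higher lists were ATF4 targets (median 0.70), p53 targets (0.62), hypoxia and glycolysis genes (0.42), mesenchymal markers (0.44, with 6 measured members) and monoamine metabolism (0.33, led by DDC). Also higher were 2 lists chosen as signs of RNA preparation and handling, replication-dependent histones (0.59) and immediate early genes (0.55). Whether preparation or handling moved them was not tested. VEGFA, which encodes the vascular growth factor, was at 229 and 493 CPM, and FN1, which encodes fibronectin, at 413 and 610 CPM. The histone gene HIST1H2BD was at 12.0 and 41.2 CPM (1.70) and the immediate early gene JUNB at 131 and 255 CPM (0.96). DNA replication (-0.39), mitosis (-0.49) and androgen-induced genes (-0.01, against a random-list median of 0.16) were lower. The call of androgen-induced genes ended with a mean CPM of at least 5 (percentile 5.83), and the mesenchymal call with the same filter or a pseudocount of 5 (95.5).

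**Figure D2:**
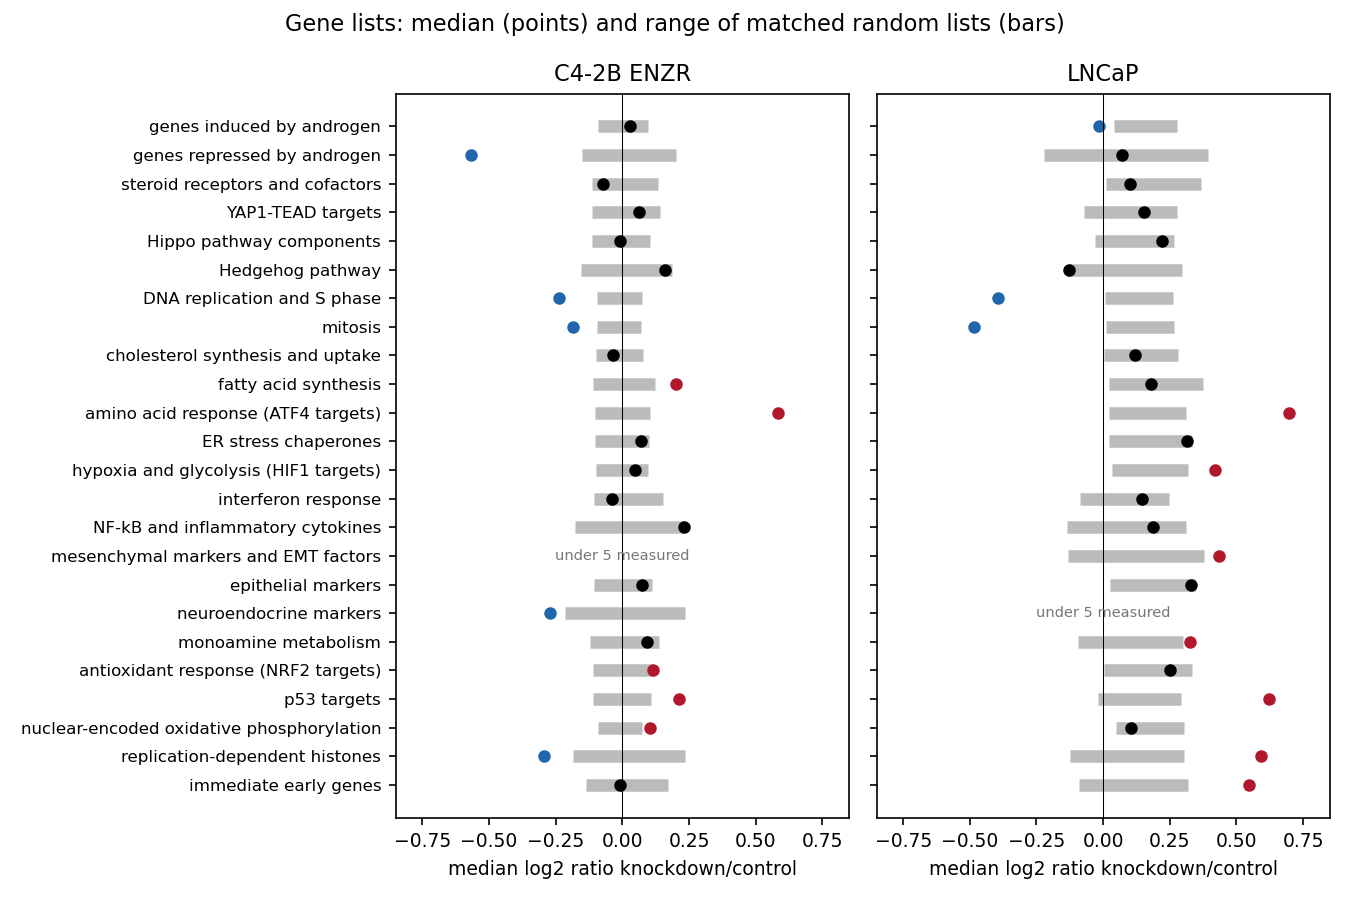
Points give the median log2 ratio of each gene list in C4-2B ENZR (left) and LNCaP (right), and grey bars the central 95% of 10000 matched random lists; red and blue points lie above and below it, black points within it. ATF4 targets and p53 targets lay above the range in both lines, and DNA replication and mitosis below it in both.

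Enzalutamide acts against androgen signalling. KLK3, the gene of prostate-specific antigen, was at 3.72 and 6.34 CPM in C4-2B ENZR and at 2391 and 2716 CPM in LNCaP. In LNCaP its log2 ratio was 0.18, and 0.05 after centring on the median ratio, with 135718 reads in the control and 132720 in the knockdown. In the mean of the 2 lines KLK3 rose in limma (log2 0.41, SE 0.12, adjusted p = 0.026). It did not pass in edgeR with the deposited scaling (adjusted p = 0.258) or with recomputed TMM (0.321). Of 22 androgen-induced genes tested over both lines 4 rose and 1 fell, the same counts when adjusted over the list alone, and 1 rose and 1 fell in edgeR with recomputed TMM. PLA2G2A rose and C1orf116 fell (161 to 98.8 CPM and 206 to 136 CPM).

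YAP1, the transcriptional effector of the Hippo pathway, was at 85.8 and 90.4 CPM in C4-2B ENZR and at 106 and 137 CPM in LNCaP and did not pass (limma adjusted p = 0.331). YAP1-TEAD targets stayed within the random range in both lines (percentiles 80.8 and 72.4), and GADD45A, a growth-arrest gene of that list, rose (log2 0.87). Hippo components were within range too (50.8 and 90.7), and VGLL4, a TEAD cofactor of that list, rose (log2 0.43, limma adjusted p = 0.0193) but did not pass in edgeR with recomputed TMM (0.0938). The Hedgehog list was at percentile 95.5 in C4-2B ENZR and 2.93 in LNCaP, where a pseudocount of 5 moved it outside the range in each line, upward (98.4) and downward (1.36). CDON, a Hedgehog co-receptor, rose (log2 0.58, limma adjusted p = 0.000993) and was the 1 of 7 members tested to pass (2 rose when adjusted over the list alone). GLI1, a Hedgehog target and effector, was at 1.46 and 3.46 CPM in C4-2B ENZR and 1.30 and 1.66 CPM in LNCaP (limma adjusted p = 0.067), GLI2 was at 0.849 and 0.447 CPM and at 2.01 and 0.921 CPM, and SHH had 3 and 9 reads in C4-2B ENZR and 0 and 2 in LNCaP.

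The last comparison asked which genes moved in the mean of the 2 lines. The medians of ATF4 and p53 targets were higher than those of matched random lists in both lines, and the medians of replication and mitosis genes were lower. The genes that rose with the smallest p were ADRA2A (mean log2 2.03, from 1.06 in C4-2B ENZR and 2.99 in LNCaP; SE 0.15, pooled over genes as all SEs here), CAMK2N1 (1.67, SE 0.12), PLA2G2A (1.93, SE 0.17), GDF15, a stress-induced cytokine (1.39, SE 0.12), and TSC22D3, a glucocorticoid-induced leucine zipper gene (1.32, SE 0.12). DDIT4 (1.48, SE 0.14) and BTG2, an antiproliferative gene (1.08, SE 0.12), rose as well. Besides MAOA, those that fell included BIRC5 (-1.48, SE 0.13), MDC1 (-1.38, SE 0.12), the replication clamp gene PCNA (-0.89, SE 0.12), the core-binding factor gene CBFB (-0.88, SE 0.13), FAM110B (-0.90, SE 0.16), DAPK1 (-0.88, SE 0.15) and ANLN, which encodes the cytokinesis protein anillin (-0.81, SE 0.12).

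Across 13114 genes the ratios of the lines had a Pearson r of 0.401 and a Spearman rho of 0.417, where genes are not independent replicates. In both lines 7 genes were 2-fold higher, against 0.150 expected from independent lists, among them ADRA2A, CAMK2N1, GDF15, PLA2G2A and TSC22D3. BIRC5 and MDC1 were the 2 genes 2-fold lower in both, against 0.0275 expected.

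**Figure D3:**
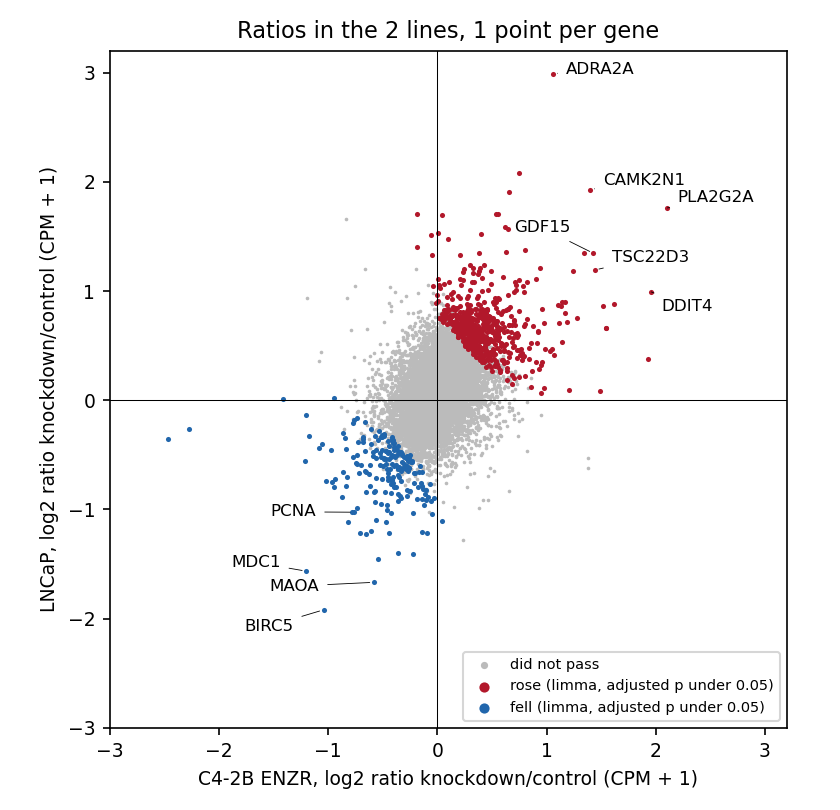
Each point is 1 of 13114 genes, with its log2 ratio in C4-2B ENZR on the horizontal axis and in LNCaP on the vertical axis; red genes rose and blue genes fell over both lines (limma), and 1 gene lies outside the axes. ADRA2A is at 1.06 and 2.99, BIRC5 at -1.04 and -1.92, and MAOA at -0.58 and -1.67.

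In limma 554 genes rose and 195 fell over both lines, and 547 and 192 of them had the same direction in each line. Of the calls, 74.0% were rises, and this share depended on the scaling: 578 rose and 543 fell after centring, 351 and 653 after rescaling to the same sum, and 175 and 128 in edgeR with recomputed TMM. With 1 residual degree of freedom the test leans on its prior (276 degrees of freedom), so genes with unlike ratios can pass, such as PPP1R10 (-0.14 and -1.20) and HIST1H2BD (-0.19 and 1.70), neither of which passed in edgeR with recomputed TMM (adjusted p = 0.0770 and 0.133). Without a filter on low values 14 genes rose and 6 fell. In all of 5 fits that differ in scaling or tool (limma as deposited, centred and rescaled, edgeR with recomputed TMM, and DESeq2), 117 genes rose and 77 fell, BIRC5, MDC1, PCNA, CAMK2N1, GDF15 and TSC22D3 among them, whereas MAOA, ADRA2A, PLA2G2A and DDIT4 did not pass in all 5. DESeq2 gave no adjusted p for 3560 of 13114 genes, and these count here as not passing. A gene outside the 5 fits may therefore lack a value rather than fail a test.

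Of 16 ATF4 targets 13 rose and none fell (14 rose when adjusted over the list alone). ATF4 itself was at 431 and 625 CPM in C4-2B ENZR and 453 and 732 in LNCaP, and ATF3, a stress-induced transcription factor, at 65.5 and 150 CPM in LNCaP. TRIB3, an inhibitor of ATF4 activity, rose (log2 0.89), PSPH did not pass, and SLC7A11, the cystine transporter, was at 86.7 and 201 CPM in C4-2B ENZR but 81.1 and 86.4 in LNCaP. Of 15 p53 targets 7 rose (11 over the list alone), with CDKN1A, which encodes the cell cycle inhibitor p21, at 92.7 and 143 and at 147 and 443 CPM. MDM2 (204 and 187 CPM in C4-2B ENZR) did not pass. Of 20 replication genes 6 fell (11 over the list alone), with PCNA at 183 and 108 and at 83.8 and 40.7 CPM and MCM5, a subunit of the replicative helicase, at -0.49, while CCNE1 did not pass at 24.3 and 24.7 CPM in C4-2B ENZR. Of 20 mitosis genes 7 fell (13 over the list alone), with PLK1 (-0.61) and CCNB1 (-0.61), 2 drivers of mitotic entry, and CDK1 did not pass at 329 and 321 and at 176 and 172 CPM. Most of these counts moved under other choices. After centring 12 replication and 15 mitosis genes fell and 14 ATF4 targets rose, while the count of p53 targets stayed at 7. In edgeR with recomputed TMM, which changes tool and scaling together, 5 replication and 5 mitosis genes fell and 11 ATF4 and 4 p53 targets rose.

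**Figure D4:**
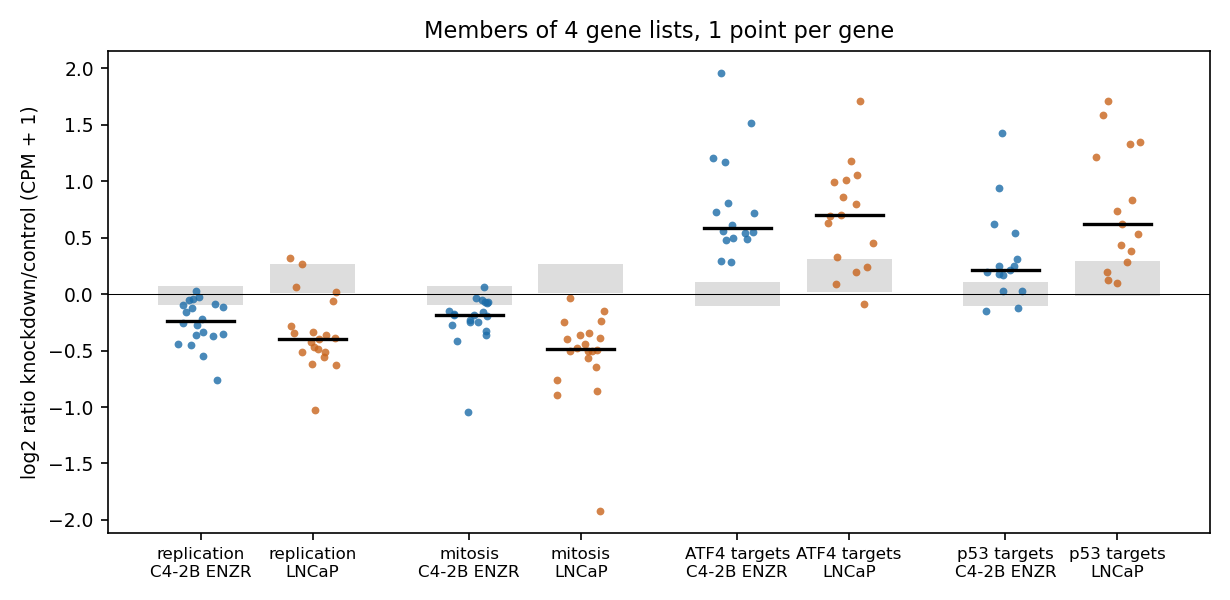
Points are the measured members of 4 gene lists with their log2 ratios in C4-2B ENZR (blue) and LNCaP (orange), black lines their medians and grey boxes the central 95% of matched random lists. Replication and mitosis medians lie below the boxes (-0.24 and -0.39, -0.19 and -0.49) and ATF4 and p53 medians above them (0.58 and 0.70, 0.21 and 0.62).

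Members of other lists passed as well. Of 16 hypoxia genes 6 rose, VEGFA (log2 1.00) and the collagen hydroxylase gene P4HA1 (0.78) among them, and of 10 monoamine metabolism genes DDC (1.42) and ALDH2, a mitochondrial aldehyde dehydrogenase, rose. Of 14 genes of the ER stress list, which are not all chaperones, HERPUD1 (0.74) and SEL1L rose. Of 14 epithelial genes CLDN4, a tight junction claudin, rose (0.90). Of 18 cholesterol genes INSIG1, which holds back sterol synthesis, rose (not in edgeR with recomputed TMM, adjusted p = 0.0659), and 1 gene fell. In edgeR with recomputed TMM 1 cholesterol gene fell and none rose. Medians of these 3 lists lay inside the random range in both lines. Interferon response (percentiles 18.1 and 78.5) and NF-kB genes (97.4 and 80.3) were within range, although NF-kB genes lay above it in C4-2B ENZR with a pseudocount of 0.1 (98.4) or unmatched random lists (99.1) and in LNCaP with a mean CPM of at least 5 (99.1), with OAS3 falling and BIRC3 and ICAM1 rising (ICAM1 not after centring, adjusted p = 0.0652, or in edgeR with recomputed TMM, 0.101). Lists called apart in 1 line had these values in the other, a difference that was not tested. In LNCaP NRF2 targets were at percentile 84.1, fatty acid synthesis at 42.4, oxidative phosphorylation at 12.1 and androgen-repressed genes at 43.4. In C4-2B ENZR hypoxia genes were at 84.5, monoamine metabolism at 90.7, immediate early genes at 39.9 and androgen-induced genes at 72.1. Steroid receptors and cofactors were at 11.1 and 17.9, cholesterol genes at 31.0 and 35.7, ER stress genes at 92.8 and 95.8 and epithelial genes at 91.0 and 96.4. Against unmatched random lists ER stress genes (99.1), epithelial genes (99.4) and the Hedgehog list (1.79) lay outside the range in LNCaP. Mesenchymal markers in C4-2B ENZR (4 measured) and neuroendocrine markers in LNCaP (3 measured) had too few members. Of 13 NRF2 targets HMOX1, which degrades heme, and SLC7A11 rose (SLC7A11 not in edgeR with recomputed TMM, adjusted p = 0.148), of 4 androgen-repressed genes the chemokine receptor gene ACKR3 fell, and none of 12 fatty acid synthesis genes passed. Markers of other cell types had under 5 measured members each. Their summed CPM went from 47.5 to 58.2 and from 56.9 to 63.7 for fibroblast markers, from 33.4 to 30.9 and from 34.4 to 37.1 for basal markers, and from 48.7 to 54.1 and from 509 to 687 for blood cell markers, of which LCP1, an actin-bundling gene named after its value was seen, rose (17.8 to 23.6 and 483 to 652 CPM) but did not pass in edgeR with recomputed TMM (adjusted p = 0.0944).

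The 7-mer TCTGTCA occurs once in the MAOA coding sequence, at bases 625 to 631 of 1581, in exon 6 of 15 (GRCh38 chromosome X, 43728294 to 43728300). It also occurs in the 3' UTRs of BIRC5 (3 copies), ANLN (2), MINPP1 (2), PCNA (1) and CBFB (1), and 10 times in the coding sequence of MDC1. DAPK1, FAM110B, TUBA1A, S100A10, SGK1, RUNX1 and ACTA2 have no copy in the 3' UTR or coding sequence. This 7-mer was picked as the most over-represented word in the 3' UTRs of the genes that fell. The shares that follow are therefore no separate test of it, and they are not adjusted for 3' UTR length. Of the genes that fell and could be searched, 79 of 179 (44.1%) hold a copy in either place, against 111 of 504 that rose and 26.3% of genes that did not pass. The share that fell was 1.19% of 8380 genes without a copy, 2.67% of 1499 with 1 copy in the 3' UTR and 5.24% of 382 with 2 or more, and the median log2 ratios of these sets were 0.01, -0.03 and -0.04 in C4-2B ENZR and 0.13, 0.11 and 0.06 in LNCaP. Of 1123 genes with a copy in the coding sequence alone 1.69% fell, with medians of -0.02 in C4-2B ENZR and 0.10 in LNCaP. RSC1A1, which also fell, shares 100% of its 50-mers with DDI2, and POC1B-GALNT4, which fell in limma but not in edgeR with recomputed TMM (adjusted p = 0.153), shares 94.0% with GALNT4.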

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

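The tests of shared sequence in this part, and the sums over gene families, were chosen after the ratios of the genes concerned were seen. Each result here was picked because the 2 lines lay on opposite sides, of 0 for a gene and of the median of random lists for a list, and no difference between the lines was tested, since each line has 1 library per group.

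Replication-dependent histones had a median log2 ratio of -0.30 in C4-2B ENZR and 0.59 in LNCaP, below and above the ranges of matched random lists. Immediate early genes were at -0.00953 and 0.55. Oxidative phosphorylation genes were at 0.10 in both lines, above the random range in C4-2B ENZR and within it in LNCaP (0.103 and 0.105 before rounding to 2 decimals). Fatty acid synthesis genes were at 0.20 and 0.18, again apart from random lists in C4-2B ENZR alone. Androgen-induced genes were at 0.0288 and -0.0137, and were apart in LNCaP alone. C7orf63 was at -1.06 and 0.44.

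GAGE2B, a cancer-testis antigen gene of a family with near-identical members, was at -2.79 in C4-2B ENZR and 4.45 in LNCaP, while the 22 GAGE genes summed were at 0.17 and 0.02. Reads that fit several copies and are divided among them differently from library to library may account for such values. Of the genes 2-fold apart, 29.6% (16 of 54 searched, 95% Clopper-Pearson interval 18.0 to 43.6) in C4-2B ENZR and 8.82% (9 of 102, 4.11 to 16.1) in LNCaP shared 50% or more of their 50-mers with another gene, against 25 of 1000 (1.62% to 3.67%) random expressed genes. Sums over copies also removed most of the difference for SSX2 with SSX2B (0.09, against -4.80 for SSX2 alone) and EIF3C with EIF3CL (-0.09, against -1.59), but not for NUDT4 with NUDT4P1 in C4-2B ENZR (1.01) or the TBC1D3 family in LNCaP (1.69). A biological difference between copies was not tested, and most genes 2-fold apart share no such sequence, so this explanation covers part of them.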

How the results depend on the processing

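The edgeR, DESeq2, GC content and length, and shared-sequence alternatives were chosen after seeing the data, as was rescaling to the same sum for the limma counts. No MAOA ratio, list median or named gene that was called reversed its direction under any alternative run. Of 40 named genes past the limma threshold, 40 kept their call after centring, 39 after rescaling to the same sum, 39 in edgeR with deposited scaling, 33 in edgeR with recomputed TMM, 18 of 27 with a value in DESeq2, and 11 without a filter on low values. Of 58 list medians, 58 kept their verdict after the GC and length correction, 56 and 53 with pseudocounts of 0.1 and 5, 50 of 53 with a mean CPM of at least 5, and 51 with unmatched random lists; centring shifts lists and random lists alike and so cannot change a verdict. Depth limits ratios of genes under about 1 CPM, and 1 library per group limits everything else. Leaving out a line leaves no residual degrees of freedom, so no such test was run.

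Counts of genes 2-fold apart moved with the pseudocount, by its construction. In C4-2B ENZR they were 90 higher and 45 lower with 0.1, 18 and 6 with 5, and 26 and 9 with a mean CPM of at least 5, and 12 were lower without genes that share 50% or more of their 50-mers. In LNCaP they were 163 and 76 with 0.1, 40 and 6 with 5, 48 and 58 after centring, and 41 and 67 after rescaling to the same sum, and 19 were lower with a mean CPM of at least 5. The LNCaP MAOA ratio was -1.80 after centring and -1.87 after rescaling. Pearson r between lines was 0.327 and 0.466 with pseudocounts of 0.1 and 5, 0.317 without a filter, 0.490 with a mean CPM of at least 5 and 0.431 after the GC and length correction; 12 genes were 2-fold higher in both lines with a pseudocount of 0.1. Lists below range in C4-2B ENZR were 3 with a mean CPM of at least 5, which leaves fewer members.

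Over both lines 14 genes rose and 6 fell without a filter, where the prior degrees of freedom dropped from 276 to 7.70. Without the trend 326 rose. After centring 578 rose and 543 fell, and after rescaling 351 rose and 653 fell. Each subtracts a positive LNCaP shift, but the prior degrees of freedom also dropped, to 75.7 and 42.7. The part of the shift alone was therefore not isolated. In edgeR with recomputed TMM 175 rose and 128 fell, and in DESeq2 131 and 90, with 3560 adjusted p-values not given. edgeR with the deposited scaling called 584 and 205. The cause of these changes was not tested, and without a filter both the prior and the number of genes tested (13114 to 20780) changed.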

Other observations

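The 6 gene lists of the first paragraph, the tests of 3' UTR composition, the fits of 7-mers in each line and the lists without members that hold CTGTCA were chosen after results were seen; the 7-mer scan and the GC and length test were set before theirs.

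Genes of the translation machinery were higher in both knockdown libraries as groups. The 77 ribosomal protein genes had a median log2 ratio of 0.23 in C4-2B ENZR and 0.42 in LNCaP (random range up to 0.07 and 0.32), and RPS2 was at 3308 and 3771 CPM and at 4052 and 5706 CPM. Of these 77 genes 1 rose (0 when adjusted over the list alone, 24 after centring). A list of translation elongation and initiation factors that also holds PABPC1 and TPT1 was at 0.25 and 0.53. Its member EEF1A1 was at 7968 and 9304 and at 8219 and 11934 CPM. Of its 12 genes 0 rose (7 when adjusted over the list alone, 7 after centring). Cytosolic chaperones were lower (-0.24 and -0.11, random lower bounds -0.09 and 0.05), and of 19 tested HSPH1 fell (-0.51, limma adjusted p = 0.00489), against 8 that fell after centring. Genes of FOXO factors and growth factor withdrawal were higher (0.25 and 0.39), and 6 of 15 rose (11 when adjusted over the list alone), TXNIP (0.84) and PIK3IP1 (1.00) among them. TSC22D3 and BTG2, named above as genes that rose, are members too, and BTG2 and SESN1 are also in the p53 list. Aminoacyl-tRNA synthetases were apart in C4-2B ENZR alone (0.21, and 0.17 at percentile 36.9 in LNCaP), a difference that was not tested, and lysosome genes were within range in both (percentiles 80.2 and 96.0), though outside it in LNCaP against unmatched random lists (98.8).

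One pattern is that the medians of replication and mitosis genes were lower, and that of ATF4 targets higher, than in matched random lists in both lines. Bias from GC content or transcript length is argued against, since all 6 medians of these 3 lists stayed outside the random range after a correction for both. Direct silencing through sites with CTGTCA, the 6-mer inside the 7-mer described next, was tested by leaving out genes that hold it in the coding sequence or 3' UTR. Mitosis genes stayed below the range in both lines with 6 members left and 14 left out (percentiles 0.10 and 0.01). Direct silencing through this word in the sequences searched therefore does not account for the lower median of those 6. The test was first written for both lists together, and split by list after 3 of 4 medians had stayed outside. The mitosis result was thus known when its own prediction was set, and it gives no verdict on the list as a whole. Replication genes stayed below the range in C4-2B ENZR (0.01) but not in LNCaP (median -0.02, percentile 6.19, 8 members left), so direct silencing may contribute there. Loss of MAOA, an indirect effect of another silenced gene and an effect of slower growth stay open.

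The other pattern is a sequence word shared by genes that fell. Of 16384 possible 7-mers, TCTGTCA was the most over-represented in their 3' UTRs, in 60 of 179 genes against 30.2 in sets matched for UTR length and expression (z = 6.95). The largest z of any 7-mer reached that value in 1.10% of 1000 random sets. TCTGTCA lies in the MAOA coding sequence, as do 8.93% of all 7-mers. The top word of the genes that rose (GAAGAGC, z = 5.10, reached by the largest z of 10% of sets) does not lie there. Fits in each line over 11385 genes, with ratios limited to 1.5 either way, are no separate test. The word was picked from these same ratios, and the bound of -5 was set after the z values were seen. In these fits TCTGTCA had the lowest z of all 7-mers ranked in C4-2B ENZR (-8.45) and in LNCaP (-9.92). The log2 differences between genes with and without it were small (-0.05 and -0.08). UTR length and GC content, entered as covariates, did not remove the lower ratios of genes with the word. This is consistent with a hairpin whose seed matches MAOA and acts on other transcripts through the same word, which may be an off-target effect shared by both lines if both received the same hairpin, although 100 of the 179 genes hold no copy in the 3' UTR or coding sequence. Loss of MAOA and silencing of BIRC5, MDC1 and PCNA by the hairpin cannot be separated with 1 hairpin per line, and an endogenous microRNA with the same seed was not tested.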
